A study of Triticum aestivum with 8 samples.

How the data were processed

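Embryos of the bread wheat cultivar Norin61 were profiled on 8 single-channel Agilent arrays, 1 array for each RNA pool. Per the labels, each pool held the total RNA of 7 embryos, and 200 ng of it was amplified and labelled with the cyanine dye Cy3. Arrays were grouped by the sample titles into dry seed (2 arrays), 16 h imbibed (3 arrays) and 24 h imbibed (3 arrays). The source names, the labelling protocol and the design text give the same hours as the titles. The description fields of the imbibed samples name 8 and 16 h in place of 16 and 24 h, so the hours rest on the titles. Per the labels' protocols, the 21 seeds of a stage were split into 3 pools; only 2 dry-seed pools were analysed here. Nothing in the labels says that the pools of a stage were grown separately, so every p-value measures only the spread between these pools, which may be partly technical.

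Each scanner file holds 43803 non-control spots for 43603 probes, of which 50 had more than 1 spot. Per the file headers, the spots were quantified with Agilent Feature Extraction 10.7.3.1, which subtracted background and removed trends within the array but scaled nothing between arrays. The intensity values used were the deposited processed signal per spot, and for 1 alternative the deposited median spot and local background intensities; all are linear. The deposited table of the series holds log2 values. Set against the scanner files, its columns equalled the log2 processed signal minus the array's 75th percentile, centred on each probe's median over the 8 arrays, so its scale, centring and direction were all resolved. The column medians of that table were 0.47 and 0.50 in dry seed, -0.05, 0.00 and -0.04 at 16 h, and -0.07, 0.00 and -0.06 at 24 h. Its columns for replicates 2 and 3 at 24 h each matched the scanner file of the other replicate. Both belong to the same group, and the scanner files were used as assigned.

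In the main setting, the log2 processed signal of each array was scaled by subtracting its 75th percentile over non-control probes. Spots with an outlier flag (3 to 15 non-control spots per array) were left out, no non-control spot was saturated, and the spots of a probe were averaged. A probe was tested if it was well above background on every array of at least 1 group and had at least 2 unflagged arrays in each group, which left 30833 probes. A probe counted as well above background on an array when at least 50% of its spots were so flagged by the scanner software. limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with a mean per group and all 8 arrays sharing 1 estimate of the spread) gave log2 fold changes, standard errors (SE) and p-values, adjusted by the Benjamini-Hochberg method within each comparison. A probe was called changed at an adjusted p below 0.05 and a change of at least 2-fold. Where a probe was not well above background on any array of a group, its change is given as a bound: the mean of the brighter group against the mean, per array of the dimmer group, of the lowest signal well above background or the probe's own signal, whichever was higher.

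The arrays carry control probes for transcripts added to the RNA in known amounts (spike-ins). Scaling to 8 such probes was an alternative set before the data were examined. The offset of an array is the median, over those probes, of the log2 deviation of each from its mean over all arrays. Values scaled to the 75th percentile describe the level of a transcript relative to the other transcripts of the array. Values scaled to the spike-ins describe it relative to the added RNA. Comparisons of a single value per array used exact two-sided permutation tests. With 2 dry-seed and 6 imbibed arrays there are 28 splits and the smallest p is 0.0357; with 3 and 3 arrays the smallest p is 0.100.

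The 8 arrays lay on 2 slides with 1 scan each. Slide 1 carried dry seed replicate 1, 16 h replicates 1 and 2 and 24 h replicate 1, and slide 2 carried the other 4 arrays, so each group lay on both slides. The slide was tested as a fixed term and fold changes were computed within each slide. The other alternatives were quantile and median scaling, the 75th percentile of probes well above background on all arrays, normexp background correction (offset 50), the deposited log2 table, no filter and a stricter filter on dim probes, keeping outlier spots, the replicate number as a block, only the 2 groups compared, a trended robust prior, array weights, no fold minimum, an adjusted p below 0.01, and leaving out each array in turn. Mean spot intensities were absent from the scanner files, so normexp was run on median intensities. The 3 comparisons between groups, their limma test and the alternatives listed above were fixed before the data were examined. Chosen after seeing the data were the comparison of wheat signal with the spike-ins, the sets of brightest probes, the counts of probes that appeared or disappeared or followed a given course over the 3 groups, the positions of single arrays, the use of a different dry-seed array for each comparison, the alternatives for all of these, and all tests of explanations in the closing section but that of mixed RNA.

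Simulated data with the fitted spreads of the 30833 tested probes, equal group means and 200 changed probes were used to test the procedure. Far more probes were called in the real data, which changes the cut-off of the adjusted p. The recovered shares therefore describe this simulated setting and not the real comparisons. At a true change of 3-fold, 79.1% of changed probes were recovered in the comparison of 16 h with dry seed, 79.1% for 24 h with dry seed and 85.1% for 24 h with 16 h. At 8-fold the recovered shares were 98.5%, 97.0% and 97.0%. False calls numbered 8, 8 and 6. The number of arrays limits the precision of every value.

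The scanner files name probes by sequence identifiers (40253 names; 965 probes carry a bare probe number) and give no gene descriptions. None of those names matched the RefSeq gene table used here (0 matches). Of 32 gene lists fixed before the data were examined, including storage protein, amylase, heat shock protein, ribosomal protein and endosperm marker lists, 0 could be filled, so no list test and no check for endosperm or aleurone RNA was run. The rule for named genes takes called probes with a functional name, highest and lowest by log2 fold change, measured on all arrays of both groups compared and with no overlap between them. Only 4 names were mnemonics rather than bare sequence numbers, and all 4 are reported. Beyond these, the 2 probes that rose most and the 2 that fell most are given by probe identifier, for each comparison.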

Results

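Mature wheat embryos were compared before imbibition and after 16 and 24 h of it, to follow how transcript levels change while the grain takes up water and germinates. Grains of the bread wheat cultivar Norin61 were kept moist in darkness at 25 °C. Only grains whose radicle, the embryonic root, had reached 3 mm at 16 h or 7 mm at 24 h entered the imbibed groups. Total RNA of 7 pooled embryos was hybridised to each array, with 2 arrays for dry seed, 3 for 16 h and 3 for 24 h. In the scanner values, replicates were close to each other across the tested probes, with a correlation of 0.990 between the dry-seed arrays, 0.985 to 0.994 among the 16 h arrays and 0.988 to 0.995 among the 24 h arrays. These correlations are across probes, which are not independent replicates.

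Dry embryos gave signal from fewer probes and less signal in all. Of 43603 probes, 25742 ± 597 (SD, n = 2) were well above background in dry seed, 30404 ± 1320 (SD, n = 3) at 16 h and 31338 ± 683 (SD, n = 3) at 24 h. The lowest signal well above background was 7.69 and 8.98 on the dry-seed arrays and 9.09 to 16.8 on the imbibed arrays (linear units). The mean unscaled 75th percentile was 256 in dry seed, 1392 at 16 h and 1583 at 24 h. Detection in dry seed thus reached less far down, and the lower count does not show that fewer transcripts were present. Relative to the spike-in probes, the 75th percentile of the wheat probes was 7.50 ± 0.13 (log2, SD, n = 2) in dry seed, 10.39 ± 0.15 (SD, n = 3) at 16 h and 11.00 ± 0.29 (SD, n = 3) at 24 h. The dry-seed level was thus 7.37-fold below that at 16 h and 11.3-fold below that at 24 h. Both dry-seed arrays lay below all 6 imbibed arrays (difference -3.19 on the log2 scale, exact two-sided permutation test, p = 0.0357, the smallest p that 28 splits allow). On slide 1 the difference was -2.91 and on slide 2 it was -3.46. From 16 to 24 h the level was 1.53-fold higher, with every 24 h array above every 16 h array (difference 0.61, exact two-sided permutation test, p = 0.100, the smallest p that 3 against 3 arrays allow). Part of that difference lay in the spike-ins, whose offset differed by -0.42 (24 h minus 16 h). Before spike-in scaling the arrays overlapped, with a log2 75th percentile of 10.21 to 10.58 at 16 h and 10.43 to 10.76 at 24 h. The unscaled 75th percentile, in linear units, gave p = 0.300 (exact two-sided permutation test). The gain in probes above background from 16 to 24 h was within the spread between replicates (difference 934 probes, exact two-sided permutation test, p = 0.400).

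**Figure D1:**
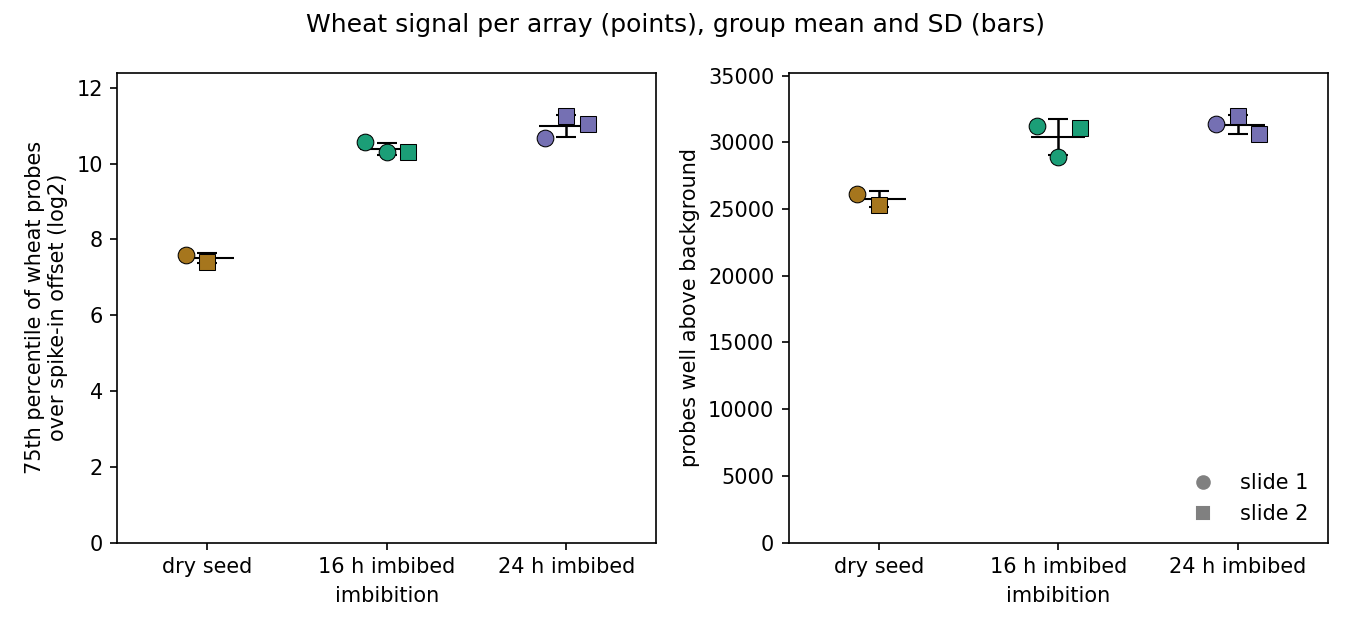
Each point is 1 array; circles are slide 1 and squares slide 2, and the bars show the group mean and SD. Left, the log2 75th percentile of wheat probes over the spike-in offset, which was 7.60 and 7.41 in dry seed and between 10.29 and 11.26 on the imbibed arrays; right, the number of probes well above background, 25320 to 26164 in dry seed and 28881 to 32004 after imbibition.

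A small set of transcripts took a large share of the signal in the dry embryo and a smaller share after imbibition. The 100 brightest probes of dry-seed replicate 1 held 23.5% of the wheat signal on the other dry-seed array, against 7.18% ± 0.12 (SD, n = 3) at 16 h and 6.73% ± 0.21 (SD, n = 3) at 24 h. In a limma fit without the array on which they were chosen, 74 of these 100 probes were lower at 24 h than in dry seed, 0 were higher and 26 were not called, against 26.8% lower and 29.0% higher among all tested probes. Relative to the spike-ins, in the fit of all 8 arrays, 46 of the 100 were lower, against 772 of all 30833 tested probes. That fit includes the array on which the 100 were chosen, which favours calls of lower. Conversely, the 100 brightest probes of 24 h replicate 2 held 10.9% ± 0.29 (SD, n = 2) of the signal in dry seed, 14.9% ± 0.59 (SD, n = 3) at 16 h and 15.7% ± 0.56 (SD, n = 2) on the other 24 h arrays. In a fit without the array that chose them, 36 were higher at 24 h than in dry seed, 7 were lower and 57 were not called, against 29.5% higher and 27.0% lower among all tested probes. The sets had 31 probes in common. Each set was picked for brightness in 1 group, so calls that favour that group are partly built in. Leaving out the choosing array does not remove this. Counted by each array's own 100 brightest spots, the share was 24.1% ± 0.70 (SD, n = 2) in dry seed. It was 15.4% ± 0.49 (SD, n = 3) at 16 h and 15.7% ± 0.48 (SD, n = 3) at 24 h.

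The 4 probes that carry a mnemonic name were all strongly expressed in dry seed relative to the imbibed embryos and fell by 16 h. The files pair these names with no description, and HSP is the usual abbreviation of heat shock protein, a family of protein chaperones that plants also make in the maturing seed. TAHSP173 fell from 7.21 ± 0.26 (log2 relative to the 75th percentile, SD, n = 2) in dry seed to 2.12 ± 0.80 (SD, n = 3) at 16 h, a 34.0-fold decrease (log2 fold change -5.09, SE 0.40, limma adjusted p = 1.47e-05), and stood at 1.52 ± 0.10 (SD, n = 3) at 24 h. TAHSPLW was well above background in dry seed (-0.04 ± 0.42, SD, n = 2) and on 0 of the imbibed arrays, so it was at least 117-fold lower at 16 h (limma adjusted p = 7.42e-07) and at least 134-fold lower at 24 h (limma adjusted p = 3.97e-07). MTTANADH2 fell 15.9-fold by 16 h (log2 fold change -3.99, SE 0.16, limma adjusted p = 6.38e-07), and TATHAUMLP 22.0-fold (-4.46, SE 0.28, limma adjusted p = 5.05e-06). Relative to the spike-ins the 16 h change of TAHSP173 was -2.20, that of MTTANADH2 -1.11 and that of TATHAUMLP -1.57 on the log2 scale, so the 3 were lower under both scalings. The fitted change of TAHSPLW was -5.03 at 16 h relative to the spike-ins. It rests on 16 h signals below background, so its size was not measured, and no bound was computed under that scaling. With normexp background correction, which was run with an offset of 50, the fitted change of TAHSPLW was -4.19 at 16 h and -4.48 at 24 h. Both are smaller than the bounds of 117-fold and 134-fold.

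In the comparison of 16 h with dry seed, which asks how far the embryo's transcripts had changed once the radicle was out, 16075 of 30833 tested probes changed, 7925 higher and 8150 lower at 16 h. That is 52.1% of the tested probes. Among called probes well above background on all arrays of both groups, the median change was 3.40-fold for those higher and 3.49-fold for those lower. The fitted change was a rise of at least 8-fold for 1925 probes and a fall of at least 8-fold for 1534, including probes below background on 1 side. Called probes included 2368 that appeared, being well above background on all 3 arrays at 16 h and on neither dry-seed array, and 197 that disappeared in the same sense. The bound on the change was at least 2-fold for 1359 of the 2368 and for all 197, and at least 8-fold for 443 and 124 of them, and with normexp background correction 322 probes appeared. Over the called probes measured on both sides, 5053 were higher and 6879 lower. Requiring signal on the dimmer dry-seed arrays drops more rises than falls, so this balance is partly set by the requirement. The largest rises measured on both sides were those of probe A_99_P532422 (379-fold, log2 fold change 8.56, SE 0.27, limma adjusted p = 2.80e-07) and probe A_99_P229621 (289-fold, 8.17, SE 0.25, limma adjusted p = 2.66e-07). The largest falls were those of A_99_P248541 (572-fold, log2 fold change -9.16, SE 0.19, limma adjusted p = 1.28e-07) and A_99_P003031 (526-fold, -9.04, SE 0.35, limma adjusted p = 5.51e-07). The size of these folds depended on the processing: in the same order, the log2 changes were 6.52, 6.22, -8.57 and -7.26 with normexp background correction and 11.45, 11.06, -6.28 and -6.16 relative to the spike-ins. Where several probes carried 1 sequence name and at least 2 of them were called, 865 of 912 names had all called probes in the same direction.

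The direction of that comparison depended on what the arrays were scaled to. Relative to the spike-ins, 27608 probes changed, 26761 higher and 847 lower at 16 h, and the median over tested probes moved from -0.06 to 2.82 on the log2 scale. Of the 8150 probes lower relative to the array's other transcripts, 847 were still lower, 4135 were higher and 3168 were not called relative to the spike-ins. With normexp background correction 24.1% of the calls were higher, and without a filter on dim probes 30.9%, against 49.3% in the main setting. It was 42.9% with only the probes above background on all 8 arrays. Each of these alternatives favours falls, since the offset, the scaled floor or the filter acts most on the dimmer dry-seed arrays. With normexp, 11386 of the 16075 main calls were called in the same direction and 938 in the opposite one. Fold changes computed within each slide correlated at 0.958 between slides across the tested probes.

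**Figure D2:**
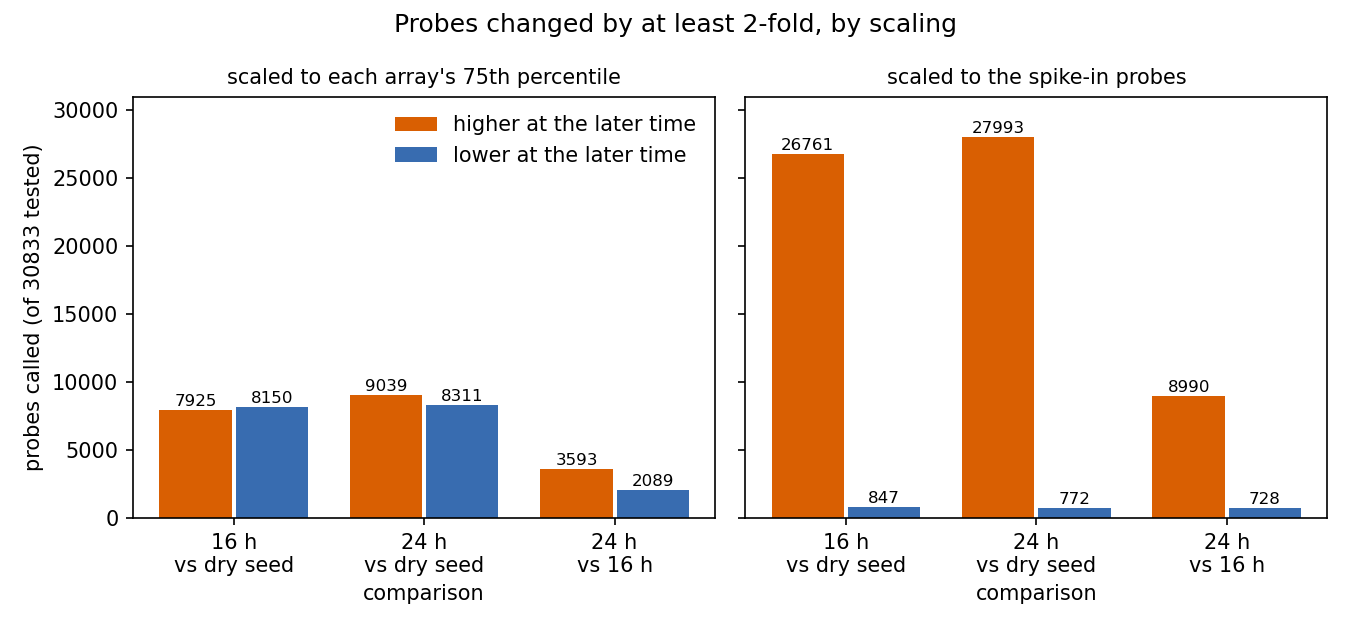
Bars give the number of probes called at an adjusted p below 0.05 and at least 2-fold, higher (orange) and lower (blue) at the later time, for the 3 comparisons on the horizontal axis. Left, arrays scaled to their 75th percentile, with 7925 higher and 8150 lower at 16 h than in dry seed; right, arrays scaled to the spike-in probes, with 26761 higher and 847 lower.

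In the comparison of 24 h with dry seed, 17350 probes changed, 9039 higher and 8311 lower at 24 h. The 4 mnemonic probes remained low, with TAHSP173 51.8-fold lower than in dry seed (log2 fold change -5.69, SE 0.40, limma adjusted p = 6.93e-06), MTTANADH2 29.2-fold lower (-4.87, SE 0.16, limma adjusted p = 2.48e-07) and TATHAUMLP 24.2-fold lower (-4.60, SE 0.28, limma adjusted p = 3.63e-06). These 24 h changes were smaller relative to the spike-ins, at -2.20, -1.38 and -1.10 on the log2 scale. The fitted value for TAHSPLW was -5.37, but it rests on 24 h signals below background, so its size was not measured. Probes A_99_P229621 (936-fold) and A_99_P532422 (885-fold) were again the 2 with the largest rises measured on both sides. The largest falls were those of A_99_P388492 (2132-fold, log2 fold change -11.06, SE 0.34, limma adjusted p = 2.07e-07) and A_99_P455482 (1886-fold, -10.88, SE 0.33, limma adjusted p = 1.95e-07). In the same order, the log2 changes were 7.91, 7.75, -9.32 and -9.06 with normexp background correction and 13.36, 13.28, -7.57 and -7.39 relative to the spike-ins. By 24 h, 3087 called probes had appeared, of which 1934 had a bound of at least 2-fold and 769 of at least 8-fold, and 275 had disappeared, all with a bound of at least 2-fold. With normexp background correction 577 appeared, with the same limit of its offset as at 16 h. The fitted change was a rise of at least 8-fold for 2672 probes and a fall of at least 8-fold for 1925, including probes below background on 1 side. Over the called probes measured on both sides, 5407 were higher and 7340 lower. As at 16 h, this balance is partly set by requiring signal on the dimmer dry-seed arrays. Relative to the spike-ins, 28765 probes changed, 27993 higher and 772 lower, with a median log2 change of 3.54 over the tested probes against 0.04 in the main setting. With normexp background correction 27.4% of the calls were higher and without a filter on dim probes 33.8%, against 52.1% in the main setting. It was 43.1% with only the probes above background on all 8 arrays. As at 16 h, each of these alternatives favours falls. Fold changes correlated at 0.972 between slides across the tested probes.

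Much of the measured difference between dry seed and 24 h was already present at 16 h. On a scale where the dry-seed mean is 0 and the 24 h mean is 1, the 5404 probes higher at 24 h, measured on both sides and with a value on all 8 arrays stood at 0.82 ± 0.05 (SD, n = 3) at 16 h, and the 7340 probes lower at 24 h stood at 0.83 ± 0.04 (SD, n = 3). These are means over probes weighted by the squared change, and the probes were chosen on the same difference that sets the scale. Over all tested probes the 16 h arrays stood at 0.77 ± 0.06 (SD, n = 3). Against dry seed, 6670 probes were higher at both times, 6632 were lower at both and 220 changed in opposite directions. Independent lists of these sizes would share 2323, 2197 and 4525 probes. The 20 simulations without any effect shared a mean of 0.05 probes, but they call few probes at all, so that count cannot show whether the 16 h and 24 h changes agree. The fold changes of the comparisons correlated at 0.895 across probes, against 0.598 in the simulations, where the shared dry-seed arrays alone produced it. The covariance was 4.18 against 0.042. With a different dry-seed array for each comparison the correlation was 0.878 or 0.869, depending on which array served which, and the covariance 4.14 or 4.11. None of these values separates a biological change from a technical shift between the dry-seed arrays and all imbibed arrays, which the closing section leaves open.

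**Figure D3:**
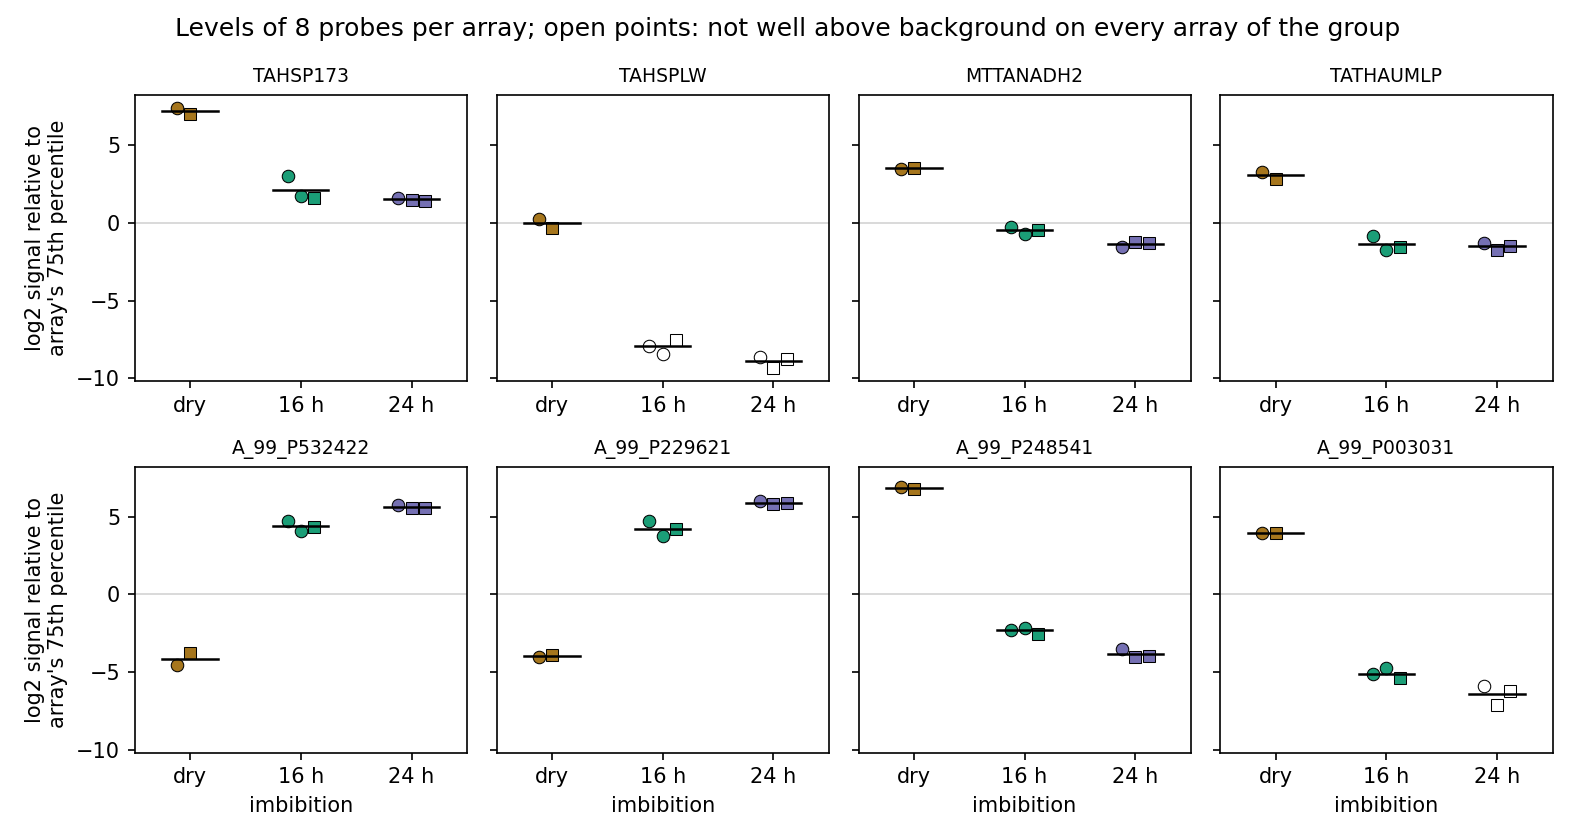
Each panel gives the log2 signal of 1 probe relative to its array's 75th percentile, with 1 point per array (circles slide 1, squares slide 2), lines at the group means and open points where the probe was not well above background on every array of the group. The upper panels show the 4 mnemonic probes, which fell by 16 h (TAHSP173 from 7.21 to 2.12), and the lower panels the 2 probes that rose most and the 2 that fell most from dry seed to 16 h.

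The comparison of 24 h with 16 h asks what changed while the radicle lengthened further. Changes were fewer, and more of them were rises: 5682 probes changed, 3593 higher and 2089 lower at 24 h. The fitted change was a rise of at least 8-fold for 652 probes and a fall of at least 8-fold for 101, including probes below background on 1 side. Called probes included 353 that appeared and 59 that disappeared, with a bound of at least 2-fold for 239 and 43 of them and of at least 8-fold for 52 and 2, and with normexp 63 appeared and 4 disappeared. Of the mnemonic probes none was called. TAHSP173 had a log2 change of -0.61 (SE 0.36, limma adjusted p = 0.190), MTTANADH2 of -0.87 (SE 0.14, limma adjusted p = 0.00265, below 2-fold) and TATHAUMLP of -0.14 (SE 0.25, limma adjusted p = 0.669). The largest rises were those of A_99_P486982 (175-fold, log2 fold change 7.45, SE 1.18, limma adjusted p = 0.00237) and A_99_P422467 (171-fold, 7.41, SE 0.86, limma adjusted p = 0.000862). Both differed widely between 16 h replicates, with log2 levels of -0.65, -5.25 and -5.06 for the former and -2.67, -5.82 and -5.05 for the latter; their log2 fold changes lay between 6.65 and 8.96 and between 6.76 and 8.34 when single arrays were left out, lowest without 16 h replicate 2 and highest without 16 h replicate 1. The largest falls were those of A_99_P208251 (38.1-fold, log2 fold change -5.25, SE 0.80, limma adjusted p = 0.00210) and A_99_P207586 (37.0-fold, -5.21, SE 0.80, limma adjusted p = 0.00209), which stood at 4.72 ± 0.54 and 4.01 ± 0.59 (log2, SD, n = 3) at 16 h and at -0.53 ± 1.82 and -1.20 ± 1.78 (SD, n = 3) at 24 h. Without 24 h replicate 2 their log2 fold changes were -6.26 and -6.16, and without 24 h replicate 1 they were -4.49 and -4.40. With normexp the log2 changes of these rises and falls were 6.42, 6.21, -5.09 and -4.95, and relative to the spike-ins 8.06, 8.02, -4.64 and -4.60. Relative to the spike-ins 9718 probes changed, 8990 higher and 728 lower, with a median log2 change of 0.60. With only the probes above background on all arrays 51.1% of calls were higher, against 63.2% in the main setting. Fold changes correlated at 0.912 between slides across the tested probes.

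Probes were followed over the 3 groups by their calls at each step. Of the probes higher at 16 h than in dry seed, 6212 had no further call from 16 to 24 h, 1088 rose again and 625 fell. Of those lower at 16 h, 6394 had no further call, 811 fell again and 945 rose. A further 1560 probes rose and 653 fell from 16 to 24 h with no call at 16 h. Without the fold minimum, many of the early changes were followed by a further call: of 23338 probes called at 16 h, 2986 rose at both steps, 3211 fell at both, 3049 rose and then fell and 2946 fell and then rose. These counts also moved with the scaling. The number that rose at both steps was 327 with normexp and 7935 with spike-in scaling, and the number that fell and then rose was 591 with quantile and 124 with spike-in scaling. Independent lists would give 924 probes that rose at both steps, 552 that fell at both, 537 that rose and then fell and 950 that fell and then rose. The steps share the 16 h arrays, and the correlation of their fold changes was 0.065 across probes, against -0.445 in 20 simulations without effects, with a covariance of 0.135 against -0.028. Relative to the spike-ins, 26460 probes were higher at both times than in dry seed and 661 were lower at both, of which 356 were lower by at least 8-fold at 24 h.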

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

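The signal below was noticed after the data were seen. A control probe outside the wheat measurements, DCP_1_11, was dim on the dry-seed arrays, at a mean log2 signal of 1.86 and 1.83 with neither of its 2 spots well above background. On 24 h replicate 2 it was at 3.88 and on 24 h replicate 3 at 3.45, each with 1 of the 2 spots well above background. On the other imbibed arrays it lay between 1.12 and 1.77. On the arrays that stood out, the spots disagreed (4.13 and 52.3 on replicate 2, 3.16 and 38.0 on replicate 3, in linear units). The cause was not tested. Other control probes differed between groups too, in either direction. GE_BrightCorner, above background on all 8 arrays, was at 10.35 and 9.98 in dry seed and 12.52 to 13.06 on the imbibed arrays. DCP_1_0 was at 18.51 and 18.43 in dry seed and 17.90 to 18.41 on the imbibed arrays. These differences were not tested.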

How the results depend on the processing

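The alternatives for the spike-in level were chosen after seeing the data, as was the count of other splits. Among the alternative values of the main results, 83 kept their size and 9 did not, by the limits used (1.5 times for a count of probes, 1 SD for a level). The counts of changed probes moved with spike-in scaling (27608 at 16 h and 28765 at 24 h against dry seed, 9718 at 24 h against 16 h). Relative to the main scaling, it added 2.88 at 16 h and 3.49 at 24 h to the log2 change of every probe against dry seed. Without a filter on dim probes 25550 and 26690 changed against dry seed; there the signal floor, once scaled, lies higher on the dimmer dry-seed arrays. At 24 h against 16 h the count was 3512 with normexp, 3310 with probes above background on all 8 arrays (fewer probes tested) and 16021 with no fold minimum. The dry-seed deficit relative to the spike-ins was -2.70 by total signal against -3.19 by the 75th percentile; the cause was not tested. Leaving out each array gave 15777 to 16121 probes (16 h against dry seed), 17108 to 17421 (24 h against dry seed) and 4944 to 6755 (24 h against 16 h, highest without 16 h replicate 1). It gave -3.28 to -3.07 for the spike-in deficit of dry seed and 0.48 to 0.77 for 24 h minus 16 h; without a dry-seed array, the remaining one is assumed to vary like the other groups. Same-numbered pools did not deviate together (r of 0.12, 0.09 and -0.04 between 16 and 24 h), and the replicate number as a block gave 16194, 17446 and 5648 probes. Both rest on the scanner files' numbers, in which 24 h replicates 2 and 3 may be exchanged. With those replicates exchanged, r would be -0.11 for 16 h replicate 2 and 0.13 for 16 h replicate 3. With the slide as a block the counts were 16019, 17395 and 5922.

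Of the values of single probes, 9 changed sign. With spike-in scaling, which adds about the median shift to every probe, these were A_99_P422467 at 16 h against dry seed (2.48, limma adjusted p = 0.00493), A_99_P208251 (0.77, adjusted p = 0.337) and A_99_P207586 (1.19, adjusted p = 0.144) at 24 h against dry seed, and, uncalled under either scaling, TAHSP173 (0.001) and TATHAUMLP (0.47) at 24 h against 16 h. The others were uncalled in both settings: A_99_P486982 at 16 h against dry seed with normexp (-0.34), TATHAUMLP at 24 h against 16 h with array weights (0.10) and without 16 h replicate 1 (0.13), and A_99_P422467 at 16 h against dry seed without 16 h replicate 2 (0.25). Over all arrays left out in turn, TATHAUMLP ranged from -0.31 to 0.13 and A_99_P422467 from -1.33 to 0.25 in these comparisons; the cause was not tested. Among the other alternatives for single probes, 952 kept direction and call, 32 lost the call and 6 gained it; among counts of probes that appeared, disappeared or followed a given course, and similar values, 261 kept their size and 25 did not. Those that moved included the 811 probes that fell at both steps (193 with spike-in scaling, 461 with normexp), the 625 that rose and then fell (379 with normexp), the 1560 that rose only after 16 h (931 with spike-in scaling, 945 with normexp) and the 653 that fell only after 16 h (78 with spike-in scaling). The real split of the 6 imbibed arrays gave 5682 probes and the other 9 splits at most 0; 1 of 10 splits was as large, and 10 splits are too few for a share below 0.05. Gene list tests and their alternatives were not run, since no list could be filled. Signal over background limits the dry-seed side: probes below it there have only bounds.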

Other observations

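The median SD of a tested probe between replicates was 0.12 (log2) in dry seed, 0.19 at 16 h and 0.15 at 24 h, and 623, 668 and 461 probes had an SD above 1. The dry-seed SD rests on 2 arrays and the others on 3. The median of an SD lies lower with fewer arrays, so these values do not rank dry seed against the other groups. Falls relative to the spike-ins were few, with 958 of 30833 tested probes lower than in dry seed at 16 or 24 h. Several probes of the same sequence name gave the same picture at 24 h, with 997 of 1045 names in 1 direction against dry seed and 354 of 355 against 16 h.

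Of the tests in this part, that of mixed RNA was set out before its result was seen, and the others after. The first pattern is the low wheat signal relative to the spike-ins in dry seed. A larger amount of added spike-in alone would leave the unscaled wheat signal equal, but the unscaled 75th percentile differed by -2.53, dry seed minus imbibed (log2; within-group SD 0.16), with -2.46 on slide 1 and -2.60 on slide 2. A few genes taking most of the signal would leave the total signal equal, yet the total relative to the spike-ins differed by -2.70 (within-group SD 0.21). Less input RNA or a poorer labelling yield in dry seed remains open, because each group had its own extraction and labelling and the spike-ins were brighter in dry seed by 0.66; it cannot be told apart from a lower share of messenger RNA in the total RNA of dry embryos, which may be the biological explanation and was not tested.

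The second pattern is that replicate 1 at 16 h lay nearer to the 24 h arrays, with a position of 0.838 on the scale from the dry-seed mean to the 24 h mean over all tested probes, against 0.741 and 0.741 for the other 16 h pools. Replicate 2, on the same slide, lay 0.097 lower, against an SD of 0.0093 in the other groups, which argues against the slide, and the gap was still 0.077 over probes above background on all 8 arrays, which argues against dim probes as the whole cause. With spike-in scaling the gap was 0.0896 and the difference from replicate 2 was 0.0987, against an SD of 0.0603 in the other groups, so there this pool did not stand apart by more than 2 SD. If 24 h RNA had been mixed into the pool, the 362 probes at least 8-fold higher at 24 h would put the mixed share at 12.3%. The 440 probes lower at 24 h by at least 2 log2 units would then shift by a median of -0.16. They shifted by -0.91, a median of -0.76 beyond that prediction, against a median difference of 0.24 between replicates 2 and 3. The 95% bootstrap interval was -0.80 to -0.72 (2000 draws). It resamples the probes of 1 pool, which are not independent, so it holds no spread between pools. No biological explanation was tested, and what set this pool apart stays open.

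The third pattern concerns the deposited log2 table. Its column for 24 h replicate 2 correlated at 1.00 with the scanner values of replicate 3 and at 0.593 with those of its own replicate, and the column for replicate 3 correlated at 0.593 with its own. The samples were thus exchanged either in the table or in the scanner files, and nothing here tells which. With that table the counts of changed probes were 16064, 17344 and 5680.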
